A study of Homo sapiens with 27 samples.

How the data were processed

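PRAISE libraries of HEK293T cells, a human embryonic kidney line, were analysed. PRAISE treats RNA with a bisulfite-type reagent that turns pseudouridine (Ψ) into an adduct read through as a deletion, so the share of reads with a deletion at a site reports its Ψ level. The labels describe small RNA purified by size after TRIzol extraction and DNase digestion, demethylated with AlkB at a molar ratio of 2, with 300 ng as input and 100 ng kept untreated. The series holds 27 samples of 9 genotypes, each with 2 treated libraries and 1 untreated library: wild type, knockouts of PUS1, PUS7, TRUB1, RPUSD1, RPUSD2 and RPUSD3, a DKC1 knockdown and its negative control. The tables used here cover 24 of these samples. The 3 RPUSD3 samples have no table that was analysed here. The pairs of treated libraries are technical replicates, so the p-values of single sites measure technical spread only. Those of list and permutation tests take sites or snoRNAs as units, not libraries.

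Per the file headers, the authors' tables give counts for each library at each site, that is, reads with a deletion and reads covering the site. The deposited difference columns are in percent, as treated minus untreated deletion rate in percentage points. In the DKC1 tables the deposited deletion rates are a fraction of the reads. The deposited column for the change after loss of the enzyme has a unit of another (other) kind, a signed difference of mean fractions. The submitters' notes name cutadapt, UMI-tools 1.0.0, BWA, SAMtools 1.14 and the GRCh38 genome without saying which step used which, and they give neither the filters on sites nor the way deletions were counted. Both are therefore unknown here. The knockout tables for PUS1, PUS7 and TRUB1 repeat the sites listed for wild type, and those for RPUSD1 and RPUSD2 hold sites that the authors named as dependent on the enzyme, so a site that is present in a knockout alone is not seen. Counts come from deposited reads, so intervals and tests of single sites cover counting error and the spread between 2 libraries.

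Levels were computed as deletions over covering reads, in percent, for each treated library, and are given as the mean ± SD of 2 libraries (n = 2). The level in the untreated library is the background and has no replicate. tRNA positions follow the conventional tRNA numbering given in the tables, and tRNAs carry the isodecoder names of the tables, which pair no genome coordinates with cytosolic tRNAs. Mitochondrial sites carry their coordinate on the mitochondrial genome, and genes for snRNA and snoRNA were located in GENCODE release 29 (GRCh38).

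Several checks changed what was used. In the DKC1 tables the deletion counts of the knockdown libraries contradicted the rates beside them: count and rate matched, within 1e-06, at 0 of 28 snRNA sites in both treated libraries and at 2 of 73 snoRNA sites in each. The product of rate and covering reads was whole within 0.02 at all 28 and 73 sites in each library, so that product was used as the knockdown count. Sites 9-12 of RNU6-1 and of RNU4ATAC appeared to have exchanged knockdown values. RNU4ATAC carried 338683 reads in knockdown replicate 1 and RNU6-1 carried 735, against 713 and 445071 in negative-control replicate 1. An exchange alone does not settle the levels. The knockdown values under RNU4ATAC had 0 deletions in 338683 and 446832 treated and 330354 untreated reads. Both sites were left out, which leaves 26 of 28 snRNA sites. The wild-type means printed in the RPUSD1 and RPUSD2 tables equalled those of the wild-type table at 0 of 16 and 0 of 3 sites within 0.001 points. Wild-type counts of the wild-type table were used for these comparisons too. The authors' own p-values and differences for the same libraries were not analysed here.

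The sites, tests, lists, thresholds and alternatives were fixed before the data were examined, except where a choice is named as made later. Each site with at least 20 reads in every treated library of a comparison was tested with a quasi-binomial model of deleted against undeleted reads. Its dispersion was moderated across the sites of the table with limma 3.58.1 (squeezeVar) in R 4.3.3 and kept at 1 or more, followed by a two-sided F test and Benjamini-Hochberg adjustment over the table. A site was called lower or higher at an adjusted p under 0.05 together with a difference of at least 10 percentage points. Adjusted p-values given for single sites come from this limma-moderated model. On simulated data of the same depth, with 20 draws per comparison, 78.4% (PUS7 cytosolic) to 93.9% (snRNA) of sites moved by 15 points were called in tables of over 10 sites, and at most 1.36% of unmoved ones.

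The 26 lists were position groups of tRNA (27/28, 34/36, other yeast Pus1 positions 1, 26, 65 and 67, 38/39, 13, 35, 30/31/32, 54 and 55), tRNA regions (anticodon stem-loop, the same without 27/28, acceptor stem, D arm, variable loop, T arm), snRNA species (U1, U2, the U2 branch-site region, U4, U5, U6, the minor spliceosome and 7SK) and snoRNA families (H/ACA, C/D and scaRNA). Fisher's exact test, two-sided, compared the share of called-lower sites in a list with that in the other tested sites of the table, with Benjamini-Hochberg adjustment over 84 tests. Sites of related tRNAs may share reads and are not independent, which the p-values of this test do not allow for. The deposited tables held 0 listed sites at positions 1, 26, 65, 67 and 54 and in 7SK. The mitochondrial table also held 0 at positions 34, 36, 13 and 35.

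Sites were named by rule. From each comparison came the 10 largest falls and 5 largest rises among called sites whose knockout or knockdown libraries both lay beyond both controls, with at most 2 per tRNA position or per snRNA or snoRNA gene. The 2 members of each list with the highest control level were added, and tables of up to 15 sites could be named in full. In wild type, the 5 positions with the most sites were named, as were the 5 highest sites outside positions 55, 39, 38, 27, 28 and 13. Medians per isoacceptor or position, and any other site, were chosen after their values were seen.

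Alternatives, each changed alone, were coverage minimums of 10 and 100, differences of 5 and 20 points, subtraction of the untreated level, limma on percentage points, Fisher's exact test on summed counts, a replicate block, each replicate left out, 1 value per isoacceptor and position, and for wild type sites of at least 20%. A replicate block with the replicate numbers crossed, a dispersion trend on depth and the exchanged snRNA sites put back were added after seeing the data. With a replicate left out, the lone library is assumed to vary like the other group. Tables and permutation tests (100000 permutations, seed 1) used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.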

Results

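Ψ levels were measured in small RNA of HEK293T cells by PRAISE, with 2 treated libraries and 1 untreated library per genotype. The deposited tables cover cytosolic tRNA, mitochondrial tRNA, snRNA and snoRNA. Over the 705 cytosolic tRNA sites, median coverage was 14202 and 14687 reads in the wild-type libraries, 20475 and 19927 in PUS1 knockout, 19301 and 24102 in PUS7 knockout, and 23011 and 24711 in TRUB1 knockout. Over the 35 mitochondrial sites the medians ranged from 437 to 656 reads per treated library. The 28 snRNA sites had medians of 5412 and 6071 reads in the negative control and 9645 and 10586 in the DKC1 knockdown, whereas the 73 snoRNA sites had 435 and 494 against 155 and 197. The 16 sites listed for RPUSD1 had medians of 564 and 354 reads in that knockout, and the 3 listed for RPUSD2 had 4256 and 5211.

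The wild-type libraries address how much Ψ each tRNA site carries. Of 705 listed cytosolic sites, 701 had at least 20 reads in both libraries, in 249 tRNAs and at 24 positions, and their median level was 61.8% with quartiles of 29.5% and 84.9%. Position 55, in the T loop, held the most sites, 238, with a median of 84.0%. Position 39, in the anticodon stem, had 118 sites with a median of 59.9%, and position 28 had 85 with 28.1%. Position 13, in the D arm, had 49 sites with a median of 62.2%, and position 27 had 46 with 43.3%. Outside these positions and 38, the highest levels were at position 72 of the acceptor stem in tRNA-Arg-TCG-4, 95.5% ± 0.387, and tRNA-Arg-TCG-2, 94.5% ± 0.233 (SD, n = 2). Anticodon position 35 of tRNA-Tyr-GTA-7 stood at 93.8% ± 0.325 and that of tRNA-Tyr-GTA-4 at 91.7% ± 0.0799, and position 72 of tRNA-Arg-TCG-5 at 91.2% ± 0.578. Over the regions, mean levels were 44.9% in the anticodon stem-loop, 70.9% in the acceptor stem, 55.7% in the D arm, 49.1% in the variable loop and 76.4% in the T arm.

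In mitochondrial tRNA, 33 of 35 listed sites passed the coverage minimum, in 15 tRNAs and at 12 positions, with a median of 61.2% and a range from 5.56% to 97.7%. The highest sites outside the positions above were position 32 of mt-TRNP at 74.1% ± 0.596 and position 40 of mt-TRNE at 57.3% ± 0.315, followed by position 40 of mt-TRNN at 12% ± 2.11, position 68 of mt-TRNF at 10.1% ± 1.05 and position 32 of mt-TRNC at 8.14% ± 1.51. Background was low: the median untreated level was 0.323% over cytosolic and 0.361% over mitochondrial sites. It exceeded 5% at 25 cytosolic sites and reached 44% at the highest. The libraries differed by a median of 0.552 points at cytosolic sites and by more than 10 points at 9 of them. Pearson's r across those sites was 0.997 and Spearman's rho 0.998, although sites are not independent replicates.

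**Figure D1:**
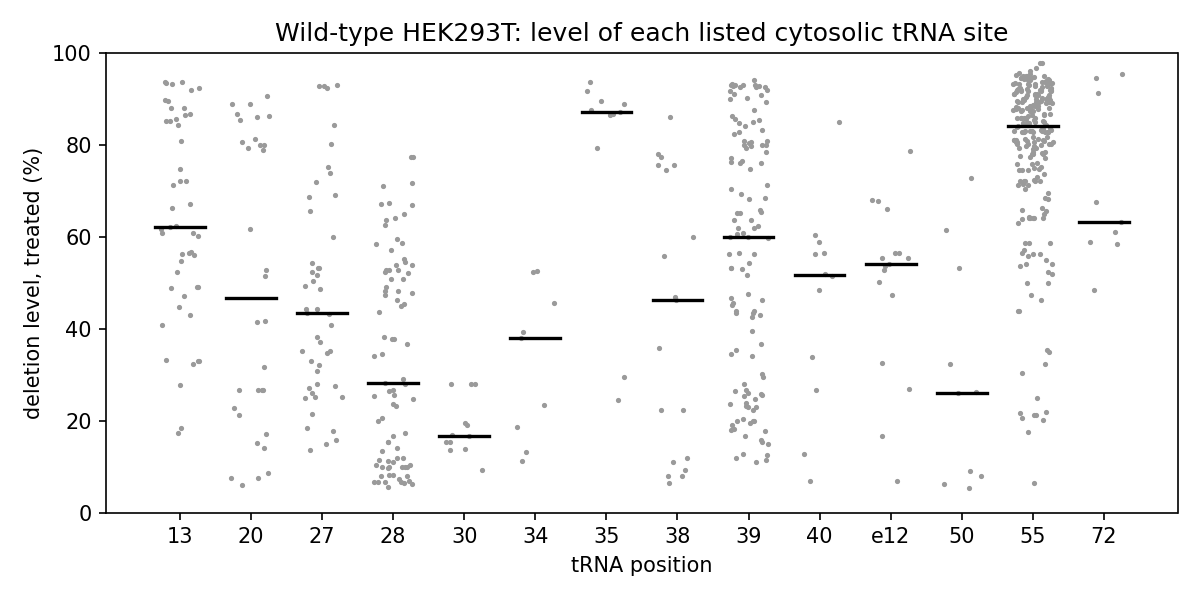
Ψ level in percent (y axis) of each tRNA site in wild-type cells by tRNA position (x axis), for positions with at least 9 sites. Each point is the mean of 2 treated libraries and black bars are medians, which run from 84.0% at position 55 down to 28.1% at position 28 among the 5 positions with the most sites.

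The PUS1 knockout addresses which sites depend on PUS1, an enzyme known for Ψ in the anticodon stem. Positions 27 and 28 fell broadly: 105 of the 131 tested members of this group were lower and their mean level went from 38% ± 0.0626 to 6.55% ± 0.0400. The 26 not called were all at position 28, with medians of 8.87% in wild type and 2.76% in the knockout, which left most of them little room for a 10-point difference. Position 27 of tRNA-Lys-CTT-3 fell from 92.5% ± 0.0680 to 10.5% ± 0.195 and that of tRNA-Lys-CTT-11 from 92.8% ± 0.297 to 15.2% ± 0.950. Position 28 of tRNA-Gln-TTG-3 and of tRNA-Gln-TTG-1 both fell from 77.4% to 9.93% and 9.94%. At the same time 46 sites elsewhere in the anticodon stem-loop rose. Position 36 of tRNA-Arg-TCT-1 rose from 15% ± 0.665 to 76.5% ± 1.87, and position 30 of tRNA-Ile-AAT-4 from 15.3% ± 0.153 to 57.4% ± 0.0609.

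Of 701 cytosolic sites tested, 112 were lower, with a median change of -35.9 points, and 54 were higher, with a median change of 19.3 points. Further rises were at position 36 of tRNA-Arg-TCT-5, from 12.6% ± 0.726 to 54.8% ± 1.98, position 39 of tRNA-Cys-GCA-15, from 36.7% ± 1.30 to 77.8% ± 0.226, and position 30 of tRNA-Ile-AAT-5, from 16.8% ± 0.00549 to 57.7% ± 0.225. Anticodon position 34 of tRNA-Val-TAC-1 rose from 52.6% to 63.7% and that of tRNA-Val-TAC-2 from 52.4% to 64.3%. Named falls outside positions 27 and 28 were smaller. They comprised position 13 of tRNA-Val-CAC-4, from 62.2% ± 2.51 to 35.6% ± 1.34, and of tRNA-Val-CAC-1, from 60.7% to 46%, position 39 of tRNA-Asn-GTT-9, from 45.6% ± 0.712 to 20.9% ± 0.241, and of tRNA-Gln-TTG-4, from 63.8% to 53.2%, and position 72 of tRNA-Arg-TCT-4, from 67.5% to 53%. Position 20 of tRNA-Asn-GTT-3 fell from 52.8% to 38.7%, on an untreated background of 39.2% and 35.7%. Background at the other named sites with a change was at most 1.44%.

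By isoacceptor, chosen after the values were seen, tRNA-Ile-AAT moved from a median of 47.4% to 3.72% at position 27, lower at 8 of 8 sites, and from 19.4% to 56.2% at position 30, higher at 8 of 8. tRNA-Met-CAT moved from 43.8% to 7.13% at position 27 and from 24.3% to 48.6% at position 31, and tRNA-Arg-TCT from 53.9% to 11.2% at position 28 and from 10.8% to 51.5% at position 36. Position 39 of tRNA-Leu-TAA was higher at 4 of 4 sites, with medians of 61.3% and 82.4%.

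The share of lower sites among positions 27/28 exceeded that among other sites (Fisher's exact test, adjusted p = 2.7e-88), and 105 members were lower when adjusted over the list alone. Positions 38/39 had 2 lower and 27 higher of 137, positions 30/31/32 had 0 lower and 13 higher of 24, positions 34/36 had 0 and 6 of 13, position 13 had 3 and 5 of 49, position 35 had 0 and 0 of 11, and position 55 had 0 and 2 of 238. These counts were the same adjusted over the list alone. By region the anticodon stem-loop had 107 lower and 46 higher of 328 (107 and 48 adjusted over the list alone), and without 27/28 it had 2 and 46 of 197. The acceptor stem had 1 lower of 9, the D arm 4 lower and 5 higher of 86, the variable loop 0 of 24 and the T arm 0 lower and 3 higher of 250, each the same adjusted over the list alone. With 105 of the 112 falls at 27/28, fewer lower sites than elsewhere were found in 5 other lists: position 55 (adjusted p = 6.2e-22), the T arm (1.8e-23), the anticodon stem-loop without 27/28 (3.5e-14), the D arm (0.0045) and 38/39 (1.5e-08, which became 0.172 with 1 value per isoacceptor and position). In the authors' deposited table, 105 of the 112 lower sites carry the label PUS1-dependent, as do 26 sites not called and 1 not tested, and all 54 higher sites the label PUS1-independent. The rise count was 24 with a 20-point threshold, and the call at position 39 of tRNA-Gln-TTG-4 was lost without control replicate 2 or knockout replicate 2.

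**Figure D2:**
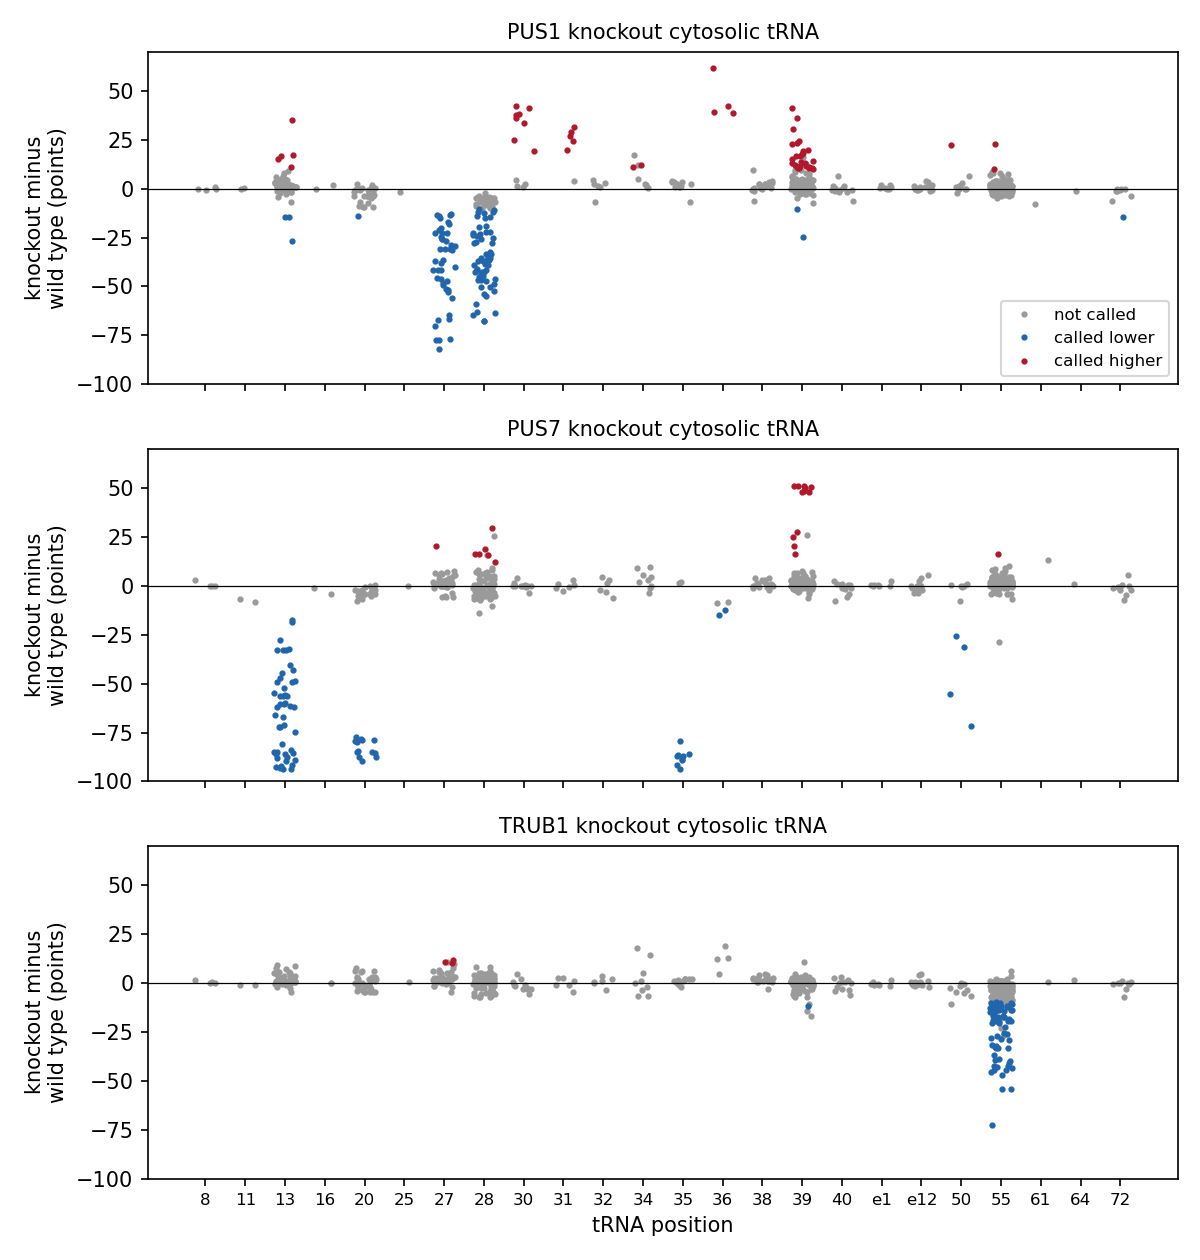
Change in Ψ level in percentage points (y axis) of each cytosolic tRNA site by tRNA position (x axis) in knockouts of PUS1, PUS7 and TRUB1, as knockout minus wild type, means of 2 treated libraries each. Falls gather at positions 27 and 28 without PUS1 (105 of 131 sites lower), at 13 without PUS7 (49 of 49) and at 55 without TRUB1 (77 of 238), and 46 sites at positions 29 to 43 are higher without PUS1.

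In mitochondrial tRNA of the PUS1 knockout, all 11 tested sites at positions 27 and 28 were lower, their mean going from 65.8% ± 1.11 to 0.937% ± 0.154. Position 27 of mt-TRNL1 (mitochondrial coordinate 3258) fell from 97.7% ± 0.118 to 2.37% ± 0.356, that of mt-TRNH (12161) from 80.1% ± 0.154 to 0.200% ± 0.282, and the joint site 27/28 of mt-TRNK (8316) from 78.9% ± 1.63 to 0.639% ± 0.184. Position 28 of mt-TRNF (605) fell from 73.5% ± 2.94 to 0%, where 444 and 456 reads allow up to 0.676% and 0.658% by counting error, and that of mt-TRNE (14718) from 48.8% to 0.132%. Position 39 of mt-TRNC (5792) fell less, from 50.9% ± 1.88 to 36.7% ± 1.22. Position 31 of mt-TRNL2 (12295) rose from 6.51% ± 2.31 to 34.7% ± 2.70 and position 32 of mt-TRNC (5799) from 8.14% ± 1.51 to 18.4% ± 0.358.

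In all, 12 of 33 sites were lower and 2 were higher. Positions 27/28 were lower more often than the rest (Fisher's exact test, adjusted p = 2.9e-07). Positions 38/39 had 1 lower of 7, positions 30/31/32 had 2 higher of 3, and position 55 had 0 of 6. The anticodon stem-loop had 12 lower and 2 higher of 23, and without 27/28 it had 1 and 2 of 12. The D arm had 0 of 1, the variable loop 0 of 1 and the T arm 0 of 6. The acceptor stem had 0 of 2, but its wild-type levels of 10.1% and 5.67% left little or no room for a 10-point difference, and their mean was 7.89% ± 1.53 in wild type and 1.01% ± 0.253 in the knockout. Every count was the same adjusted over the list alone. Untreated levels in wild type were at most 0.757% at the sites named as changed. Rises numbered 1 when either control replicate was left out. In the authors' deposited table, 11 of the 12 lower sites are labelled PUS1-dependent, as are 2 sites not called and 1 not tested.

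The PUS7 knockout addresses which sites depend on PUS7, known for Ψ at position 13 and, in tRNA-Tyr, position 35. All 49 sites at position 13 were lower, and their mean went from 64.3% ± 0.00470 to 0.186% ± 0.00466. Position 13 of tRNA-Pro-AGG-1 fell from 93.8% ± 0.634 to 0.209% ± 0.0124 and position 35 of tRNA-Tyr-GTA-7 from 93.8% ± 0.325 to 0.319% ± 0.0343. Losses of like size were seen at position 20 of tRNA-Leu-CAG-2, from 90.6% ± 0.0516 to 1.27% ± 0.0326, and position 50 of tRNA-Arg-CCT-4, from 72.9% ± 0.434 to 0.948% ± 0.0156. In tRNA-Tyr, position 39 rose where position 35 fell: in tRNA-Tyr-GTA-3 from 15.3% ± 0.0219 to 66.4% ± 1.6.

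Of 700 sites tested, 77 were lower, with a median change of -77.5 points, and 20 were higher, with a median change of 26.1 points. Among further falls, position 13 of tRNA-Glu-TTC-14 went from 93.7% ± 0.251 to 0.291% ± 0.0543, position 35 of tRNA-Tyr-GTA-4 from 91.7% to 0.321%, position 20 of tRNA-Leu-CAG-1 from 88.9% to 1.25%, and position 50 of tRNA-Arg-ACG-2 from 61.5% ± 1.22 to 6.25% ± 0.384. Position 36 of tRNA-Arg-TCT-1 fell from 15% ± 0.665 to 0.138% ± 0.0194 and that of tRNA-Arg-TCT-5 from 12.6% ± 0.726 to 0.0469% ± 0.0664. Further rises were at position 39 of tRNA-Tyr-GTA-6, from 15.9% ± 0.412 to 67% ± 1.29, position 28 of tRNA-Gln-CTG-5, from 37.8% ± 0.703 to 67.2% ± 0.0740, position 27 of tRNA-Val-TAC-3, from 13.6% ± 1.55 to 33.9% ± 3.70, and position 28 of tRNA-Arg-TCT-1, from 49.2% ± 0.848 to 68.0% ± 1.52. Untreated levels at these sites were at most 2.90%. Over tRNA-Tyr-GTA, in medians chosen after they were seen, position 35 went from 87.5% to 0.302%, lower at 9 of 9 sites, and position 39 from 12.7% to 62.3%, higher at 8 of 8.

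Position 13 and position 35 had larger shares of lower sites than other sites (Fisher's exact test, adjusted p = 4.3e-54 and 3.1e-07). For position 35, where 9 of 11 were lower, the adjusted p was 0.554 with 1 value per isoacceptor and position. The 9 all lie in tRNA-Tyr-GTA and make 1 value there, so that setting leaves too few values to decide. The D arm had 62 lower of 86 (adjusted p = 1.4e-52). The counts adjusted over the list alone were the same for these 3 groups. Positions 27/28 had 0 lower and 7 higher of 130 (1 and 8 adjusted over the list alone), positions 38/39 had 0 and 12 of 137 (0 and 11), position 55 had 0 and 1 of 238 (0 and 0), positions 34/36 had 2 and 0 of 13 (the same), and positions 30/31/32 had 0 and 0 of 24 (the same). The anticodon stem-loop had 11 lower and 19 higher of 327, and without 27/28 11 and 12 of 197. The T arm had 4 lower and 1 higher of 250, the acceptor stem 0 of 9 and the variable loop 0 of 24, each the same adjusted over the list alone. The authors' deposited table labels 100 sites PUS7-dependent, which comprise all 77 lower sites and 23 not called here, and it labels the 20 higher sites PUS7-independent. Some sites not called had wild-type levels that left no room for a 10-point fall. Among them, 2 at position 36 went from a median of 8.81% to 0.0277% and 2 at position 11 from 8.05% to 0.426%. The PUS7 knockout libraries differed by a median of 1.32 points from each other. Rises numbered 9 without either control replicate, and the calls named above for tRNA-Arg-TCT and for position 27 of tRNA-Val-TAC-3 were lost without either control replicate.

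**Figure D3:**
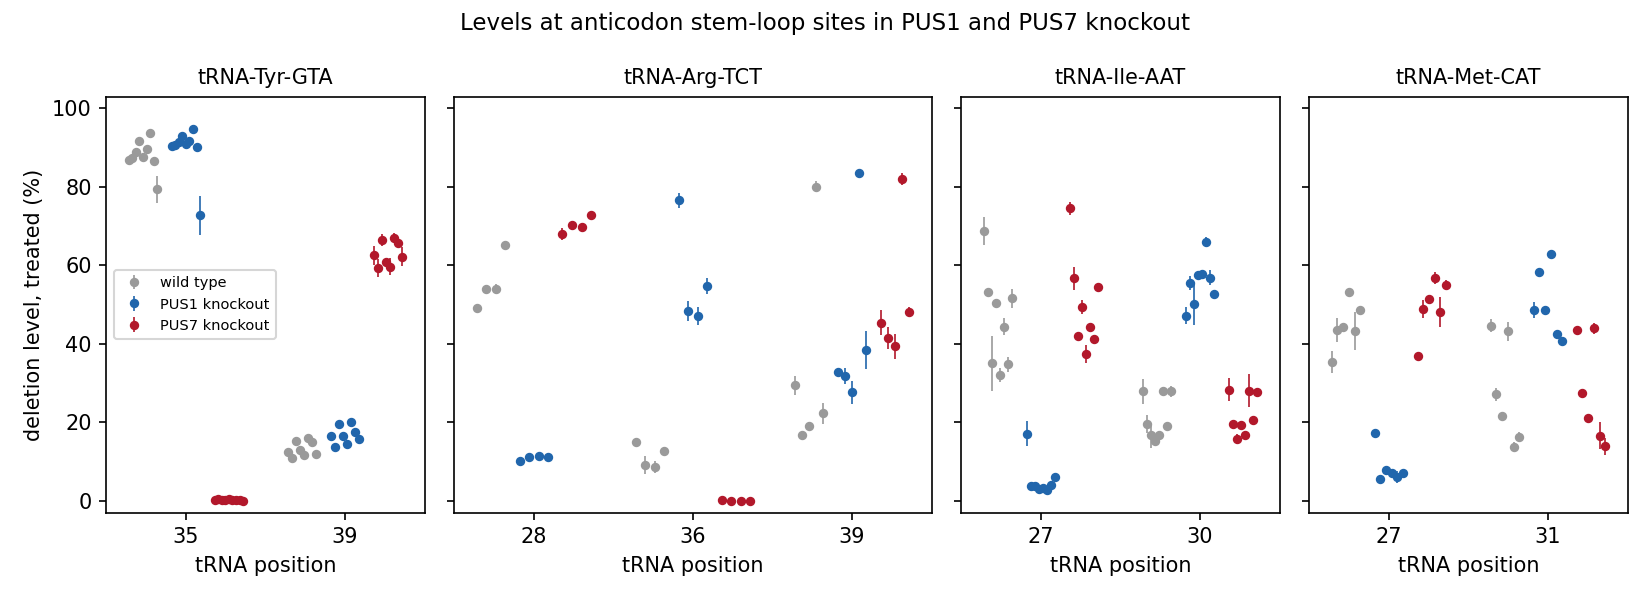
Ψ level in percent (y axis) at paired positions of the anticodon stem-loop in tRNA-Tyr-GTA, tRNA-Arg-TCT, tRNA-Ile-AAT and tRNA-Met-CAT, in wild type, PUS1 knockout and PUS7 knockout, with error bars as the SD of 2 libraries. Where one position was lost another stood higher, as in tRNA-Tyr-GTA without PUS7, where the median of position 35 went from 87.5% to 0.302% and that of position 39 from 12.7% to 62.3%.

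In mitochondrial tRNA of the PUS7 knockout, 0 of 33 sites were called in either direction by the limma-moderated test, 4 had an unadjusted p under 0.05, and limma on percentage points and Fisher's exact test on summed counts called 0 each. Position 27 of mt-TRNL1 stood at 97.7% ± 0.118 in wild type and 98.1% ± 0.285 in the knockout, position 55 of mt-TRNL1 at 94.6% ± 0.0483 and 95.6% ± 0.432, and position 39 of mt-TRNH at 84.5% ± 0.567 and 82.7% ± 0.338. All list counts were 0, also adjusted over the list alone: 0 of 11 at positions 27/28, 0 of 7 at 38/39, 0 of 3 at 30/31/32, 0 of 6 at 55 and in the T arm, 0 of 23 in the anticodon stem-loop, 0 of 12 in it without 27/28, 0 of 2 in the acceptor stem (wild-type mean 7.89%), and 0 of 1 each in the D arm and variable loop. Untreated levels at these 3 sites were at most 0.757%. On simulated data at this depth, 84.8% of sites moved by 15 points were called. The table holds 0 sites at position 13 and 0 at position 35.

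The TRUB1 knockout addresses which sites depend on TRUB1, an enzyme of the family known for Ψ at position 55. At that position 77 of 238 sites were lower and the mean level went from 78.6% ± 0.0486 to 68.6% ± 0.342. Position 55 of tRNA-Glu-TTC-2 fell from 82.9% ± 0.188 to 9.99% ± 0.0354 and that of tRNA-Glu-CTC-2 from 84.8% ± 0.124 to 30.6% ± 0.259. In contrast, position 55 of tRNA-Gly-GCC-3, 97.7% ± 0.149 in wild type and 88.6% ± 1.13 in the knockout, was not called. Among isoacceptors chosen after their values were seen, tRNA-Lys-TTT had medians of 82.9% and 38.9%, lower at 7 of 7 sites, and tRNA-Thr-AGT had 83.0% and 43.4%, lower at 6 of 6.

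In all, 78 of 701 sites were lower, with a median change of -17.6 points, and 3 were higher, with a median change of 10.8 points. Position 55 of tRNA-Ile-AAT-9 fell from 97.9% ± 3.03 to 65.4% ± 1.38. The lone fall elsewhere was at position 39 of tRNA-Asn-GTT-9, from 45.6% ± 0.712 to 33.5% ± 0.553. The rises were at position 27 of 3 tRNA-Lys-TTT members, as in tRNA-Lys-TTT-5, from 52.3% ± 0.470 to 64.0% ± 1.79, and tRNA-Lys-TTT-3, from 54.3% ± 0.586 to 65.1% ± 1.46. Untreated levels were at most 1.39% at the sites named as changed. Position 55 held more of the lower sites than other positions (Fisher's exact test, adjusted p = 6.6e-38), with 78 lower adjusted over the list alone, and the T arm had 77 of 250 (79 adjusted over the list alone). Positions 27/28 had 0 lower and 3 higher of 131 (the same adjusted over the list alone) and positions 38/39 had 1 lower of 137 (0). The anticodon stem-loop had 1 lower and 3 higher of 328 (the same), and without 27/28 1 lower of 197 (0). Counts were 0 in both directions, also adjusted over the list alone, at positions 34/36 (13 sites), 13 (49), 35 (11) and 30/31/32 (24), and in the acceptor stem (9), D arm (86) and variable loop (24). The 4 sites at position 36 stood higher although none was called, with medians of 10.8% in wild type and 21.3% in the knockout. Their knockout levels, 19.8% to 31.3%, all lay above their highest wild-type level. In the authors' deposited table, 28 sites are labelled TRUB1-dependent, of which 13 were called lower here, while 65 sites called lower are labelled independent. The fall count was 132 with a 5-point and 31 with a 20-point threshold, and rises went from 2 to 6 with a knockout replicate left out and to 10 by Fisher's exact test. The calls in tRNA-Ile-AAT-9 and tRNA-Asn-GTT-9 were lost without either control replicate.

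In mitochondrial tRNA of the TRUB1 knockout, position 55 was lower at all 6 sites, with a mean of 70.8% ± 0.116 in wild type and 2.70% ± 0.0955 in the knockout. Position 55 of mt-TRNL1 (mitochondrial coordinate 3285) fell from 94.6% ± 0.0483 to 3.04% ± 0.410 and that of mt-TRNS1 (7464) from 89.6% ± 0.786 to 9.65% ± 0.785. Position 28 of mt-TRNS1 (7489) rose from 39.1% ± 0.419 to 53.2% ± 4.20 and position 40 of mt-TRNE (14706) from 57.3% ± 0.315 to 67.8% ± 0.317. The 6 falls and 2 rises were the calls among 33 sites, and position 55, which is also the whole T arm list of 6, had the larger share of falls (Fisher's exact test, adjusted p = 3.3e-06). Positions 27/28 had 1 higher of 11, the anticodon stem-loop 2 higher of 23 and the same without 27/28 1 higher of 12. Positions 38/39 (7 sites) and 30/31/32 (3), the acceptor stem (2), D arm (1) and variable loop (1) had 0 calls. All were the same adjusted over the list alone, and the authors' deposited table labels those 6 sites TRUB1-dependent. Untreated levels were at most 0.435% at the 4 sites named. With a 20-point threshold the rises numbered 0.

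**Figure D4:**
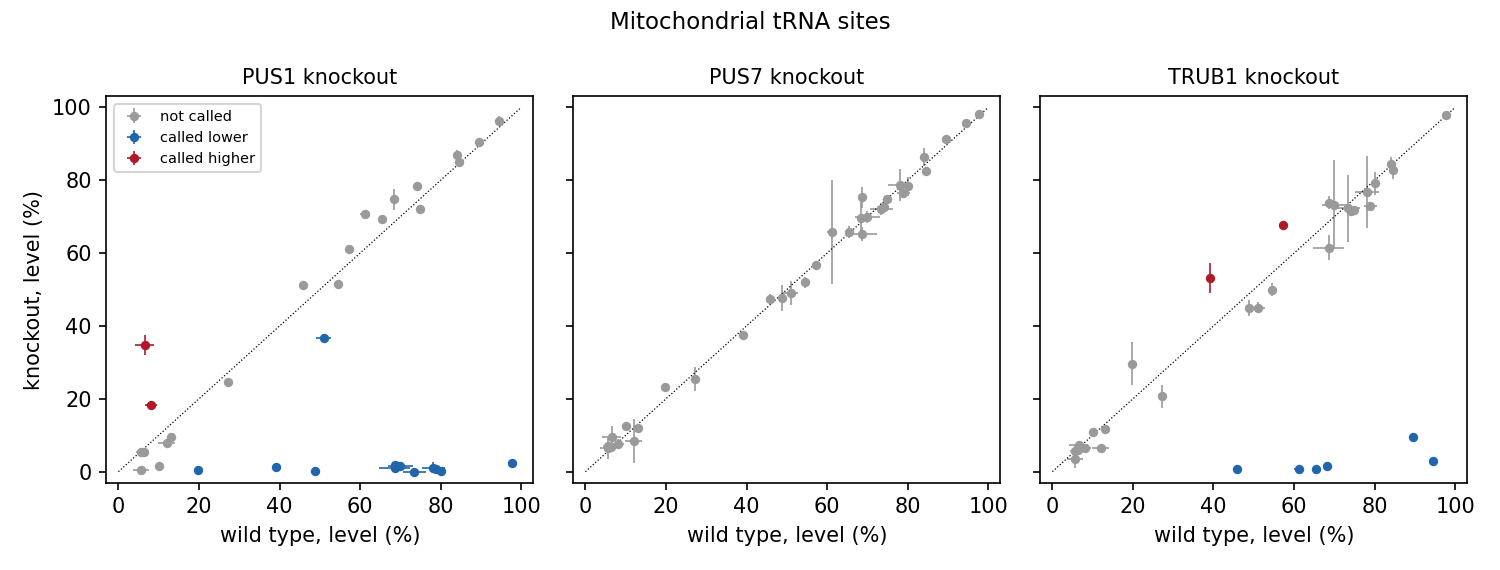
Ψ level in percent of mitochondrial tRNA sites in knockouts of PUS1, PUS7 and TRUB1 (y axes) against wild type (x axes), with error bars as the SD of 2 libraries. The 11 sites at positions 27 and 28 lie near 0 without PUS1 (mean 0.937%), the 6 at position 55 without TRUB1 (mean 2.70%), and no site is called without PUS7.

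The RPUSD1 and RPUSD2 knockouts address the substrates of enzymes of the RluA family. The authors' deposited table holds only sites that they chose as dependent on these libraries, so the direction of the counts is not independent evidence. For RPUSD1, all 16 listed sites were lower, with a median change of -27.2 points. Position 72 of tRNA-Arg-TCG-5 fell from 91.2% ± 0.578 to 0.459% ± 0.649 and that of tRNA-Arg-TCG-2 from 94.5% ± 0.233 to 4.02% ± 0.892. At position 30, tRNA-Ile-AAT-6 fell from 28% ± 0.426 to 0.505% ± 0.464, tRNA-Ile-AAT-12 from 27.9% ± 3.19 to 0.417% ± 0.589 and tRNA-Ile-AAT-8 from 27.9% ± 1.38 to 1.02% ± 0.520. Position 39 of tRNA-Arg-TCT-5 fell from 22.3% ± 2.68 to 6.78% ± 3.26, a call lost when either knockout replicate was left out. By list, 9 of 9 sites at positions 30/31/32, 1 of 1 at 38/39, 10 of 10 in the anticodon stem-loop (the same sites without 27/28) and 6 of 6 in the acceptor stem were lower, the same adjusted over the list alone. With a 20-point threshold 9 sites were lower.

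For RPUSD2, position 32 of mt-TRNP (mitochondrial coordinate 15992) fell from 74.1% ± 0.596 to 2.95% ± 0.0803. The other listed sites did not reach a 10-point difference: position 32 of mt-TRNC stood at 8.14% ± 1.51 in wild type and 1.22% ± 0.00907 in the knockout, and position 31 of mt-TRNL2 at 6.51% ± 2.31 and 0.571% ± 0.607. All 3 belong to positions 30/31/32 and to the anticodon stem-loop, with 1 lower also adjusted over the list alone, and 3 were lower with a 5-point threshold. Untreated levels in both knockouts and in wild type were at most 2.68% at the sites named for RPUSD1 and RPUSD2.

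The DKC1 knockdown addresses which sites of snRNA and snoRNA depend on DKC1, or dyskerin, the Ψ synthase of H/ACA ribonucleoproteins. In snRNA 10 of 26 sites were lower and 3 were higher. Position 79 of RNU4-2, a U4 snRNA, fell from 49.7% ± 2.85 to 10.3% ± 0.311 and positions 40-43 of RNU5A-1, a U5 snRNA, from 62.4% ± 0.496 to 28% ± 0.202. In the U6 snRNA RNU6-1, positions 85-86 fell from 61.5% ± 0.588 to 29.2% ± 0.344 and position 40 from 67.4% ± 0.223 to 42.0% ± 0.716. The 3 rises were at position 46 of RNU5A-1, from 14.7% ± 0.246 to 52.5% ± 0.485, and, in the U2 snRNA RNU2-1, at positions 53-55, from 12.7% ± 1.42 to 35% ± 1.46, and 58, from 10.6% ± 1.37 to 27.4% ± 1.82.

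The genes lie in GRCh38 on chromosome 12 (RNU4-2, 120291763 to 120291903), 15 (RNU5A-1, 65296051 to 65296166, and RNU6-1, 67839939 to 67840045) and 17 (RNU2-1, 43233787 to 43233977). Further falls were at positions 70-73 of RNU4-2, from 57.0% to 36.1%, position 89 of RNU2-1, from 55.3% to 35.9%, positions 5-6 of RNU1-1, from 35% to 16.0%, positions 82-83 of RNU6ATAC, from 53.1% to 39%, positions 91-92 of RNU2-1, from 14.6% to 3.76%, and positions 10-12 of RNU5A-1, from 13.1% to 2.44%. Sites not called included position 54 of RNVU1-2A at 97.6% ± 0.188 in the negative control and 97.1% ± 0.321 in the knockdown, position 19 of RNU12 at 94.5% and 93.0%, and positions 31-32 of RNU6-1 at 79.7% and 78.7%. Untreated levels were at most 1.29% at the called sites. At position 54 of RNVU1-2A, not called, they were 9.09% in the negative control and 6.60% in the knockdown. U1 had 1 lower of 3, U2 had 2 lower and 2 higher of 9, U4 had 2 lower of 3, U5 had 2 lower and 1 higher of 5, U6 had 2 lower of 3 and the minor spliceosome snRNAs 1 lower of 3, the same adjusted over the list alone. The U2 branch-site region had 0 of 3, with positions 43-44 at 13.8% ± 0.286 in the negative control and 18.7% ± 1.83 in the knockdown. Its positions 34 and 41 stood at 5.47% and 5.51% in the negative control, which left no room for a 10-point fall. In the knockdown they stood at 7.22% and 8.58%. No snRNA list had an adjusted p under 0.05 by Fisher's exact test. The authors' deposited table labels 9 of the 10 lower sites DKC1-dependent, with 1 site not called and the 2 left out, and gives the 3 higher ones no label. With a 20-point threshold 5 sites were lower.

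**Figure D5:**
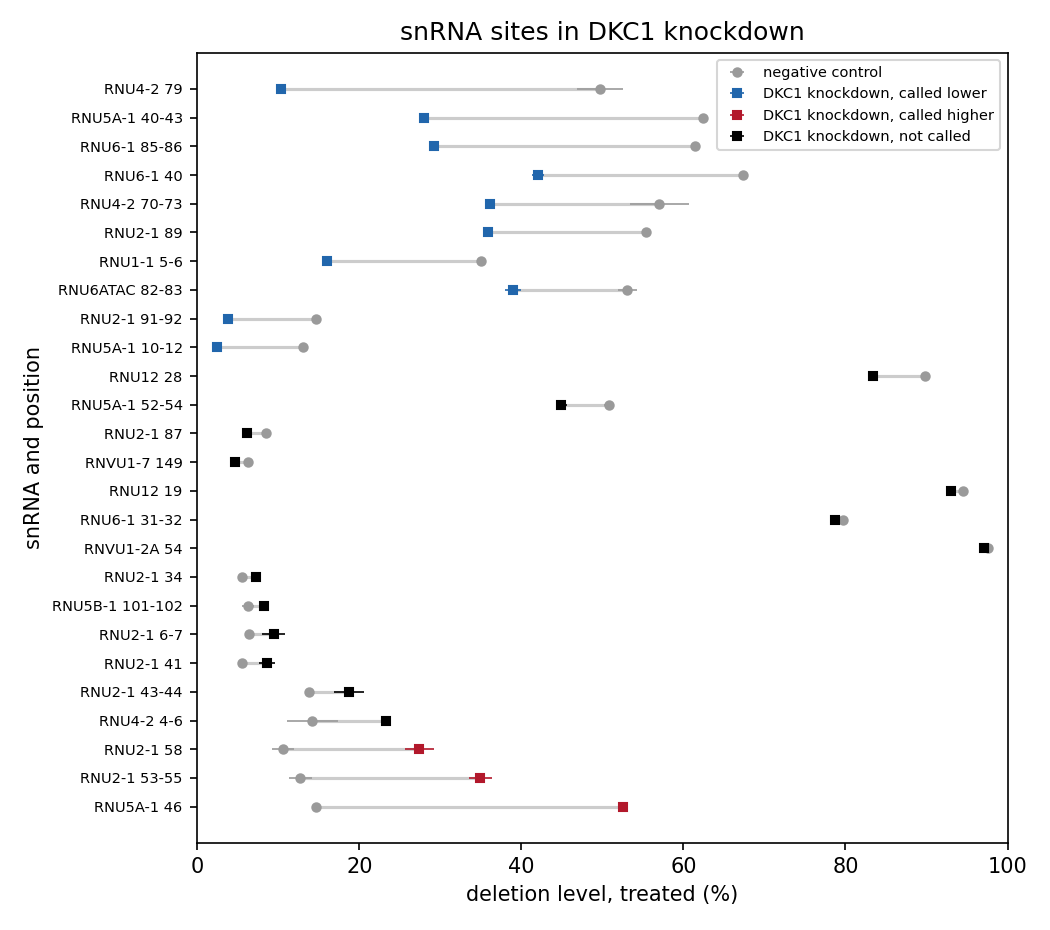
Ψ level in percent (x axis) of snRNA sites (y axis) in the negative control and the DKC1 knockdown, with error bars as the SD of 2 libraries. Sites of RNU4-2, RNU5A-1, RNU6-1 and others stand lower in the knockdown, while position 46 of RNU5A-1 goes from 14.7% to 52.5%.

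In snoRNA, 17 of 62 sites were lower and 0 were higher. Limma on percentage points and Fisher's exact test on summed counts also called 0 rises. By the limma-moderated test 44 sites had an unadjusted p under 0.05 and 43 an adjusted p under 0.05, all with a lower level in the knockdown. Low control levels left some no room for a 10-point fall, such as position 10 of SNORD118, from 9.59% to 1.78%, and positions 65-66 of SNORD83B, from 8.92% to 1.84%. With a 5-point threshold 35 were lower. Positions 72-73 of SNORD13 fell from 65.7% ± 3.17 to 9.82% ± 0.167, position 51 of SNORD16 from 72.5% ± 0.709 to 32.7% ± 0.146, and positions 82-84 of SNORA38 from 77.2% ± 3.75 to 32.2% ± 5.83. In SNORD118, the U8 snoRNA, positions 107-108 fell from 47.2% ± 2.12 to 24.2% ± 0.271 and positions 21-22 from 36.7% ± 0.145 to 14.0% ± 0.123. Of the C/D family, which guides ribose methylation, 12 of 27 sites were lower and the mean went from 32.2% ± 0.963 to 16.1% ± 1.47. Of the H/ACA family, which guides Ψ formation, 5 of 32 were lower, with means of 32.6% ± 1.04 and 25.7% ± 0.777.

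Further falls were at positions 57-59 of SNORD45A, from 81.1% ± 10.8 to 29.4% ± 2.48, position 27 of SNORD32A, from 68.2% to 22.3% ± 9.75, positions 104-107 of SNORA74A, from 48.2% ± 0.305 to 19.9% ± 0.185, positions 31-33 of SNORD92, from 40.5% ± 1.02 to 14.4% ± 1.62, and position 43 of SNORD21, from 48.1% ± 3.71 to 31.2% ± 0.786. Not called were positions 104-106 of SNORA13, 91.7% and 86.2%, positions 84-85 of SNORA75, 86.5% and 86.3%, positions 39-40 of SNORD21, 91.3% and 89.0%, and the scaRNA sites of SCARNA11, 33.1% and 32%, and SCARNA27, 25% and 27.9%. Untreated levels at the named snoRNA sites were at most 1.62%. Fisher's exact test gave an adjusted p of 0.0306 for the C/D list, which became 0.083 with a 20-point threshold, and 0.114 for H/ACA, while scaRNA had 0 lower of 3. The counts were the same adjusted over the list alone. The authors' deposited table labels 48 sites DKC1-dependent, of which 16 were among the 17 lower ones, 24 were not called and 8 were not tested. Falls numbered 7 without either knockdown replicate, when those named in SNORD45A, SNORD32A, SNORA38 and SNORD21 were no longer called, and 9 with at least 100 reads.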

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

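The tests of rises against neighbouring deletions, of snoRNA depth and of snoRNA falls at any depth were chosen only after the results were seen. Predictions for the tests of wild-type pairs, of tRNA-Tyr depth and of falls that missed the threshold were written before those tests were run. The rises and unequal falls that they address had, however, already been seen. Some sites moved in opposite directions in different knockouts, and the differences between knockouts were not tested directly. Against wild type, 1 site at position 27 of tRNA-Val-TAC was lower without PUS1 and higher without PUS7, as were 6 sites at position 28 of tRNA-Arg-TCT, tRNA-Gln-CTG, tRNA-Val-AAC and tRNA-Val-TAC, but without either control replicate only 1 of these, position 28 of tRNA-Gln-CTG-5, kept both calls. In the reverse direction, higher without PUS1 and lower without PUS7, were 5 sites at position 13 of tRNA-Gln-CTG, tRNA-Val-AAC and tRNA-Val-TAC (4 without control replicate 1 and 3 without control replicate 2), 2 at position 36 of tRNA-Arg-TCT (0 without either control replicate) and 1 at position 50 of tRNA-Arg-CCG. All these sites, in both directions, kept both calls when a knockout replicate was left out. Position 27 of tRNA-Lys-TTT was lower without PUS1 and higher without TRUB1 at 3 sites. Position 55 was higher without PUS1 and lower without TRUB1 at 2 sites, of tRNA-Cys-GCA and tRNA-Lys-CTT, and at most 1 of them kept both calls with a replicate left out. Position 30 of tRNA-Ile-AAT was higher without PUS1 and lower without RPUSD1 at 8 sites, and position 28 of mt-TRNS1, 1 site, was lower without PUS1 and higher without TRUB1.

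In tRNA, sites rose, mostly in the anticodon stem-loop, in part where a site up to 12 nt away was lost. Lost means called lower, or at most 50% of its level left at an adjusted p under 0.05. No listed site was lost so near 12 of the 54 cytosolic rises without PUS1 and 5 of the 20 without PUS7. Nor was one lost near 3 of 3 cytosolic and the 2 mitochondrial rises without TRUB1. Rises with none lost so near include positions 13, 50 and 55 without PUS1 and position 55 without PUS7, outside the stem-loop. A candidate technical explanation is that a read shows at most 1 of several nearby deletions, so that loss of one uncovers the other. Against it as a general limit, 72 of 224 pairs of wild-type sites at most 12 nt apart (32.1%) had levels that sum to over 100% by more than their SD. The share varied with distance: 24 of 42 pairs at 12 nt and 6 of 10 at 5 nt, but 0 of 23 at 3 nt and 0 of 5 at 6 nt. At 3 nt, as between positions 27 and 30 of tRNA-Ile-AAT-12, no pair thus argued against the limit. Listed sites alone are argued against at positions 28 and 39 of tRNA-Arg-TCT without PUS7. There the control level minus the least they allow was -7.27 points (median of 6 sites, SD 3.02, calls lost without either control replicate). They are also argued against at position 39 of tRNA-Leu-TAA-2 and tRNA-Leu-TAA-4 without PUS1 (-13.5 points, SD 1.19). Both cases leave sites that are not listed. Loss of reads with several deletions in the alignment would need the depth of tRNA-Tyr to rise by 1.28 on the log2 scale relative to other tRNAs without PUS7, and the median over 8 tRNAs was -0.0233 (SD 0.525), although tRNA-Tyr-GTA-7 alone reached 1.45. Hidden deletions in part of the reads cannot be told apart from a gain of Ψ at position 39 of tRNA-Tyr without PUS7 (control 6.05 points above the level for independent deletions, but 4 of 8 pairs summing to over 100%) or, without PUS1, at positions 30 and 31 (-6.42 points), position 36 of tRNA-Arg-TCT (-13.2 points) and position 39 of other tRNAs (2.12 points), where each median lay above the least level allowed although 2 of 13, 1 of 4 and 2 of 23 sites were below it by more than their SD. A biological candidate, that loss of Ψ made by one enzyme lets another modify the same stem-loop more fully, stays open and untested, since the tables hold no counts of deletions per read.

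In snRNA, position 46 of RNU5A-1 rose in the DKC1 knockdown next to the lost positions 40-43, and positions 53-55 and 58 of RNU2-1 rose too. For RNU5A-1, the control level minus that for independent deletions shown at most 1 per read was -5.06 points (combined SD of the levels 0.736). The control was, however, 14.7 points above the least level allowed if every deletion at positions 40-43 was lost. They were not all lost: the change there was -34.4 points (SE 0.481), against a rise of 37.8 points (SE 0.427) at position 46. Uncovering by positions 40-43 alone, with at most 1 deletion shown per read, is thus argued against. Positions 52-54, not called, also changed by -5.86 points (SE 0.632). With that site included, hidden deletions cannot be told apart from a gain of Ψ. For RNU2-1, 0 of the 2 other listed sites within 12 nt were lower, and sites that the table omits keep hidden deletions open there. A gain of Ψ by an enzyme other than DKC1 may account for these rises, and no data here test it.

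In snoRNA, 12 of 27 C/D sites and 5 of 32 H/ACA sites were lower in the DKC1 knockdown, and the difference in calls between the families was not tested directly. Low depth may hide some H/ACA falls: of 32 H/ACA sites not called lower, counting the 5 untested for low coverage, 2 had a fall of at least 10 points (6.25%, binomial SD 4.28), both in SNORA67 and under 20 reads in the knockdown. As the whole cause it is argued against, since over all listed sites whatever their reads 7 of 37 H/ACA and 16 of 30 C/D sites had such a fall, a difference of -34.4 percentage points (permutation p = 0.0066). Depth itself moved: the median log2 depth, knockdown over control, differed between 27 H/ACA and 20 C/D snoRNAs by -2.17 in treated and -1.95 in untreated libraries (permutation p = 2e-05 and 7e-05), which is in line with less H/ACA snoRNA in the knockdown cells. That the H/ACA snoRNAs left in these cells might be those still bound and modified stays open and untested.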

How the results depend on the processing

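The crossed replicate block, the dispersion trend on depth and the exchanged snRNA sites put back were chosen after seeing the data. No result reversed under any alternative run. Of the main counts and medians, 213 values under alternatives stayed within 1.5 times the reported count, or within the replicate spread of the median, and 33 moved. Among named sites and lists, 2437 kept their direction and side of the threshold, 70 lost the call and 10 gained it. The crossed block had no run for RPUSD1 and RPUSD2, and depth limits the snoRNA and some mitochondrial sites most. The cause was not tested where no reason is given.

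For wild-type cytosolic sites the median was 62.9% at a coverage of 100, 71.4% over sites of at least 20% and 55.1% with 1 value per isoacceptor and position, which leaves 174 values. The mitochondrial median was 65.4% at a coverage of 100, 69.3% over sites of at least 20%, and 58.9% to 62.2% without a replicate. A threshold changes counts by construction. At 20 points, rises numbered 24 (PUS1 cytosolic), 1 (PUS1 mitochondrial), 13 (PUS7 cytosolic), 0 (TRUB1 cytosolic) and 0 (TRUB1 mitochondrial), and falls 31 (TRUB1 cytosolic), 9 (RPUSD1), 5 (snRNA) and 9 (snoRNA). At 5 points, rises numbered 4 (PUS1 mitochondrial) and 10 (TRUB1 cytosolic), and falls 132 (TRUB1 cytosolic), 3 (RPUSD2) and 35 (snoRNA). At a coverage of 100, with fewer sites tested, snoRNA falls numbered 9. TRUB1 cytosolic rises were 9 with limma on percentage points, 10 by Fisher's exact test and 9 with the dispersion trend, and PUS7 cytosolic rises were 13 with the crossed block. Without a replicate, rises ranged from 1 to 2 (PUS1 mitochondrial), 9 to 28 (PUS7 cytosolic, 9 without either control replicate) and 2 to 6 (TRUB1 cytosolic), and snoRNA falls from 7 to 20 (7 without either knockdown replicate). With the exchanged snRNA sites put back, 12 sites were lower. That count takes in sites 9-12 of RNU6-1, whose knockdown level then had 0 deletions in 338683 and 446832 reads. This is below the 0.133% of the untreated negative control, so it may not be a measured level. Of the list tests, 30 had an adjusted p under 0.05, 32 at 20 points and 20 with 1 value per isoacceptor and position.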

Other observations

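The test of isoacceptors at position 55, the medians per isoacceptor and the counts of shared sites were chosen only after the results were seen. In the PUS7 knockout, all 13 lower sites at position 20 lay in tRNA-Leu, with medians going from 89.7% to 1.26% in tRNA-Leu-CAG, from 86.1% to 1.33% in tRNA-Leu-CAA, from 80.4% to 1.21% in tRNA-Leu-AAG and from 81.3% to 1.37% in tRNA-Leu-TAG. The 4 lower sites at position 50 lay in tRNA-Arg. In the PUS1 knockout, position 27 was lower at 46 of 46 sites and position 28 at 59 of 85. Every change at position 28 was downward (-67.5 to -2.10 points), and the 26 sites there that were not called had medians of 8.87% in wild type and 2.76% in the knockout, so most left little room for a 10-point difference; position 28 of tRNA-Ser-CGA-3 had the highest, 28.1% and 18.3%. Position 39 rose without PUS1 in tRNA-Phe-GAA at 3 of 3 sites, with medians of 68.5% and 83.2%, in tRNA-Lys-TTT at 5 of 6, with 45.1% and 54.3%, and in tRNA-Ser-GCT at 5 of 6, with 25.1% and 35.6%. Position 13 rose there in tRNA-Val-TAC at 3 of 4 sites, whereas in tRNA-Val-CAC it fell at 3 of 6. In the RPUSD1 knockout, position 72 of tRNA-Arg-CCT was lower at 4 of 4 listed sites, with medians of 59.9% and 1.04%.

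Position 55 fell by unequal amounts in the TRUB1 knockout, and the hypothesis that the fall follows the isoacceptor was tested on the 238 sites. Isoacceptors, 47 in all, held 75.2% of the variance of the change, against at most 42.3% with permuted labels (permutation p = 1e-05, the smallest they can give), which is consistent with it. Medians went from 82.9% to 38.9% in tRNA-Lys-TTT, from 83.9% to 34% in tRNA-Glu-CTC, from 95% to 58% in tRNA-Asp-GTC and from 84.6% to 63.1% in tRNA-Thr-CGT, while tRNA-Met-CAT had 89.1% and 88.6% with 1 of 7 sites lower. Near-identical genes of an isoacceptor may share reads, so its sites are not independent, and no feature of these tRNAs was tested.

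Of sites tested in both knockouts, 7 were lower without PUS1 and higher without PUS7, where independent calls would give 3.17, and 8 were higher without PUS1 and lower without PUS7, where they would give 5.94. Neither excess held without either control replicate: the first count became 1 each time, against 1.43, and the second 5 and 4, against 5.09 and 4.90. With knockout replicate 1 or 2 left out, both stayed. The first count was then 9 each time, against 4.47 and 3.65, and the second 8 each time, against 5.79 and 5.46. For PUS1 and TRUB1, 3 sites were lower without PUS1 and higher without TRUB1, against 0.479, and 2 were higher and lower, against 6.01; for PUS7 and TRUB1 both opposite counts were 0, against 0.330 and 2.23. The PUS1 and PUS7 knockouts both lowered 3 sites, where independent calls would give 12.2, the PUS1 and TRUB1 knockouts 1, against 12.5, and the PUS7 and TRUB1 knockouts 0, against 8.58. All share the 2 wild-type libraries, which cannot be split, so part of any excess in the same direction could come from them, whereas errors in shared controls do not favour opposite directions. Simulated comparisons with shared controls and no changed sites gave overlaps of 0, but they hold hardly any calls and so show nothing about sites that moved. The PUS7 knockout libraries differed from each other by a chi-square of 355 per cytosolic site, against 8.17 in wild type, 6.00 in the PUS1 knockout and 23 in the TRUB1 knockout.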
